A study of Homo sapiens with 4 samples.

How the data were processed

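The study measured microRNAs (miRNAs) in CCRF-CEM, an established human T lymphoblast line derived from acute lymphoblastic leukaemia. Total RNA that kept its small RNA fraction was isolated with a column kit and labelled with Cy3, per the labels' protocols. It was read on 4 single-colour Agilent miRNA arrays. Of these, 2 held the parental line, labelled replicates 1 and 2. One array held a subclone resistant to and grown in 100 nM bortezomib, an inhibitor of the proteasome, and 1 held a subclone resistant to and grown in 200 nM, after several weeks with the drug per the labels. Each array was assigned to its group from its title. Nothing in the labels says that the parental replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

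The scanner images were read with Agilent Feature Extraction version 10, per the submitters' processing notes. The deposited table gives 1 log2 signal per miRNA and array. The values themselves show that the authors had already quantile normalized them, because the bright probes of all 4 arrays take the same set of values. The deposited table lists 744 probes, namely 719 human miRNAs, 18 viral miRNAs and 7 control probes. Each array has 1 lowest value shared by 542 to 574 probes, here called its floor, which ran from a log2 signal of -3.32 to -3.17. The lowest floor is the log2 of 0.1. The median of each column equalled its floor, at -3.32 and -3.17 for parental replicates 1 and 2, -3.32 for the 100 nM subclone and -3.24 for the 200 nM subclone. How probes were summarised per miRNA, how undetected signals were treated and the array design are not given in the sources used here. A second deposited table holds the authors' own log2 ratios of each subclone over the parental line for 47 miRNAs, restricted to changes of at least 2-fold, after quantile normalization per the file headers. How the 2 parental arrays were combined in that table is not given in the sources used here.

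A miRNA was called measured on an array where its value lay above that array's floor. The arrays' lowest measured values differed, and the highest of them, a log2 signal of 1.99, is called the common limit. The table of values holds measured signals below that limit on 3 of the arrays, for 32, 30 and 11 human miRNAs on parental replicate 1, the 100 nM subclone and the 200 nM subclone. Fold changes that involve such values are not read as sizes in the text. For a miRNA measured on both arrays of 1 kind and neither of the other, the fold is a bound, "at least N-fold", the mean of the bright side over the common limit. The bound uses the common limit in place of each array's own lowest measured value, which is lower on 3 arrays and equal to it on parental replicate 2. It assumes that a signal at the floor lay under the common limit, which is not shown. On parental replicate 2, miR-512-3p and miR-32* lay at the floor, while replicate 1 read 3.64 and 3.44.

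The 75th percentile over the miRNAs measured on all 4 arrays was a log2 signal of 7.20 on every array, so the deposited scaling was kept. Values were used on the log2 scale as deposited, with no pseudocount. The 188 human miRNAs measured on at least 2 of the 4 arrays were tested. The resistant subclones together were compared with the parental line by limma (version 3.58.1, in R 4.3.3) with lmFit and eBayes, 2 arrays against 2, with 2 residual degrees of freedom. Each subclone against parental, and the 200 nM against the 100 nM subclone, came from a 3-group limma fit in which the spread is that of the parental pair alone, with 1 residual degree of freedom. A single resistant array is assumed there to vary like the parental arrays. Apart from the permutation test on neighbouring genes, which was one-sided and unadjusted, tests between arrays were two-sided, and p was adjusted by Benjamini-Hochberg with a threshold of 0.05. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333, so none is reported.

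The same count of miRNAs at least 2-fold from both parental arrays in both subclones was made for the other 2 ways of splitting the arrays into pairs. The agreement of the subclones was measured as the covariance and correlation of their log2 fold changes across miRNAs. Beside it stands the value from 1000 simulated pairs of unchanged arrays set against the same parental pair, since both comparisons share those controls. The parental pair is too small to be split into sets of at least 2.

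Before the data were examined, the design, the alternatives, 29 miRNA lists and the rule for naming miRNAs were fixed. The rule takes the 10 rising and 10 falling miRNAs with the largest smallest-of-4 difference between resistant and parental arrays, among those measured on all 4. It takes up to 5 measured on both resistant arrays and no parental array, and up to 5 the other way. For each subclone it takes the 5 rising and 5 falling by the difference to the nearer parental array, and for the 200 nM against the 100 nM subclone the 5 higher and 5 lower. It also admits any miRNA of the authors' deposited table and any list member as an example. The alternatives called common limit and without equal parental values were added after seeing the data.

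The lists are families and clusters (miR-17~92, miR-106a to miR-363, miR-106b~25, let-7 with miR-98, miR-29, miR-15/16, miR-181, miR-23/27/24, miR-221 with miR-222, miR-30, miR-26, miR-34 with miR-449, the chromosome 14q32 and chromosome 19 clusters, and the X-linked miR-506 to miR-514 cluster), themes (NF-kB responsive, T-ALL oncogenic, lymphoid, bortezomib response in myeloma, hypoxia and stress) and markers of 9 cell types. Lists with at least 3 tested members, 16 in all, were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry beside it. For each subclone alone, a list's median was placed among 10000 random lists of the same size matched on mean level.

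Names are those of the array, without the species prefix and version suffix. To find neighbouring miRNA genes, names were matched to the human RefSeq gene table of assembly GRCh38.p14, where 151 of the 188 tested miRNAs matched 1 gene. Genes within 10000 bases of each other were counted as neighbours. No coordinates are given, because the deposited tables name no genome build.

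The procedures were tested on simulated data, in 50 runs with 20 miRNAs changed at each size. These data were the real parental means plus normal noise with the moderated spreads of the fit of 2 arrays against 2. Of 188 miRNAs, the comparison of 2 arrays against 2 recovered 43.6%, 69.0% and 80.2% of changes of 1, 2 and 4 on the log2 scale, and called 1.17% of unchanged ones. The comparison of the 100 nM subclone with parental recovered 0.90%, 8.0% and 49.3%, and called 0.609% of unchanged ones. The simulated arrays had no floor and no equal parental values, while 41 of the 188 real miRNAs had equal parental values. The simulated shares therefore do not describe calls on such miRNAs or on miRNAs at a floor. Alternatives covered the scaling between arrays, the filter on dim probes, the floor, the moderation of variances, the threshold, the source of the spread, the list test and each array left out in turn. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. Viral and control probes entered no comparison between groups.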

Results

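MicroRNA levels were measured in CCRF-CEM, a T lymphoblast line from acute lymphoblastic leukaemia, and in 2 subclones of it that grow in the presence of the proteasome inhibitor bortezomib. The 4 arrays comprised 2 of the parental line, 1 of the subclone resistant to 100 nM bortezomib and 1 of the subclone resistant to 200 nM. Of 719 human miRNAs on the array, 192 and 161 were measured above the floor in parental replicates 1 and 2, 189 in the 100 nM subclone and 173 in the 200 nM subclone. In all, 145 human miRNAs were measured on all 4 arrays and 504 on none. The parental arrays differed by a median of 0.085 on the log2 scale over the 145, with an SD of 0.52, and the other pairs of arrays had SDs of 0.78 to 0.91. The number of arrays limits the precision throughout.

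The series compares the resistant subclones with the parental line. In both subclones 5 miRNAs were measured that lay at the floor on both parental arrays. The largest of these was miR-96, at a log2 signal of 5.10 in the 100 nM and 5.52 in the 200 nM subclone, at least 9.97-fold above the parental line (limma, adjusted p = 0.0025). Its 2 neighbours in the human gene table, miR-182 and miR-183, which are made from the same primary transcript, were also measured in both subclones alone, at least 1.98-fold and 1.52-fold higher (adjusted p = 0.0018 for each). miR-22 was at least 5.08-fold higher (adjusted p = 0.0029), with 4.54 in the 100 nM and 4.12 in the 200 nM subclone, and miR-1228* at least 1.91-fold higher (adjusted p = 0.0018). The adjusted p of these 5 come from floor values, whose parental spread is only the gap between 2 floors. Their folds are bounds only if the parental signals lay under the common limit, which is not shown. With values under the common limit raised to it, limma gave adjusted p of 0.0142 for miR-96 and 0.0217 for miR-22, miR-182 and miR-1228*. It gave 0.0378 for miR-183, and there too the parental values show no measured spread. In the other direction, miR-1237 was measured on the parental arrays alone, at 2.47 and 2.25, at least 1.29-fold above both subclones, and its call (adjusted p = 0.0025) was lost when all values under the common limit were raised to it (adjusted p = 0.167).

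Among miRNAs measured on all 4 arrays, 2 rose and 4 fell. miR-181c, a member of the family that tunes T-cell receptor sensitivity in thymocytes, rose 3.60-fold, from 2.95 and 2.94 on the parental arrays to 4.72 and 4.86 in the 100 nM and 200 nM subclones (log2 fold change 1.85 ± 0.0996 SE, adjusted p = 0.0131 by limma). miR-595 rose 2.77-fold, from 2.80 and 2.81 to 4.27 in both subclones (1.47 ± 0.081 SE, adjusted p = 0.0131). miR-210, the main miRNA induced by hypoxia, fell from 7.06 on both parental arrays to 5.47 and 5.42 (log2 fold change -1.61 ± 0.0834 SE, adjusted p = 0.0131). miR-23a and miR-27a, neighbours in 1 cluster, both fell, miR-23a with a log2 fold change of -1.45 ± 0.0933 (adjusted p = 0.0179) and miR-27a with -1.51 ± 0.132 (adjusted p = 0.0369). miR-652 fell from 4.67 and 4.51 to 3.46 and 3.44 (-1.14 ± 0.108 SE, adjusted p = 0.043).

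In total 12 of the 188 tested miRNAs passed, 7 higher and 5 lower in the resistant subclones, and 38 had an unadjusted p under 0.05. With each array centred on its median, 10 passed, 7 higher and 3 lower, without miR-27a (limma, adjusted p = 0.0562) and miR-652 (limma, adjusted p = 0.066). All 12 lay on 1 side of both parental arrays in both subclones. Their sign with a parental array left out was therefore fixed in advance. No call was left without parental replicate 2 (23 had an unadjusted p under 0.05), and 7 without parental replicate 1, of which 4 were among the 12 (miR-182, miR-183, miR-1228* and miR-1237), while all 12 kept their sign in both cases. With only 1 subclone in the fit, the spread came from the parental pair alone, and 37 to 43 miRNAs passed, including 10 of the 12, without miR-23a and miR-652.

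**Figure D1:**
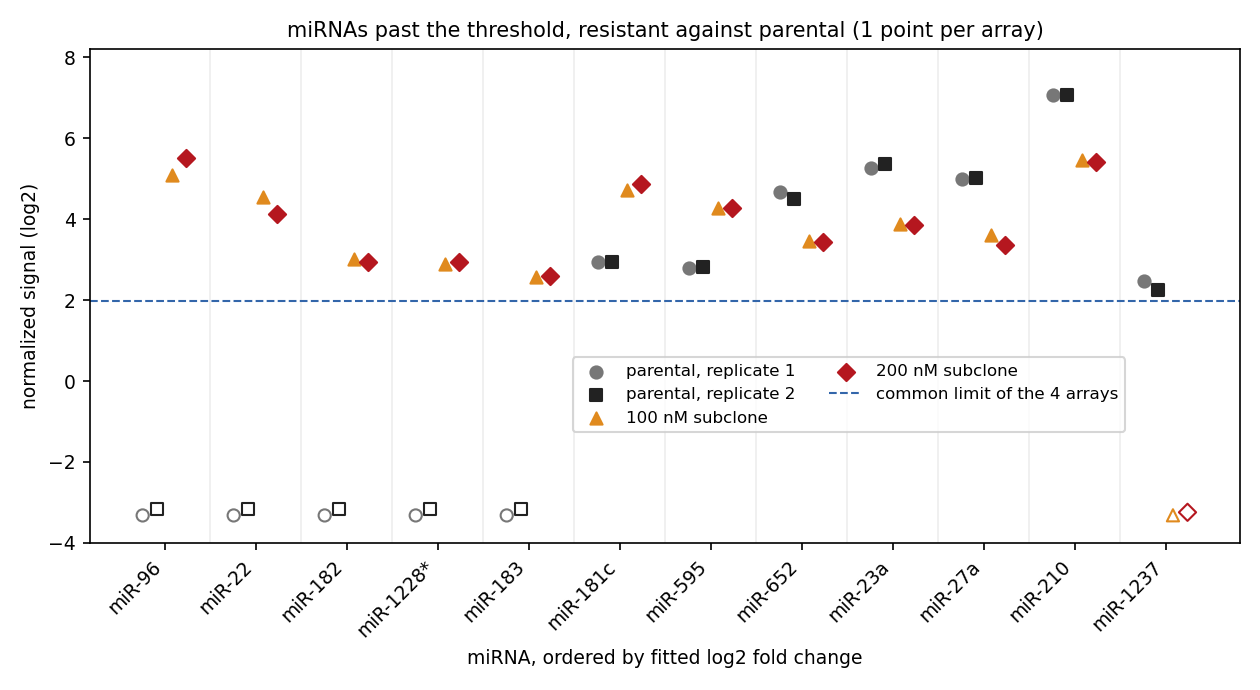
Normalized log2 signal (vertical axis) of the 12 miRNAs past the threshold in the comparison of resistant with parental arrays (horizontal axis), 1 point per array; open symbols are values at an array's floor and the dashed line is the common limit of 1.99. The parental arrays lie at the floor for miR-96, miR-22, miR-182, miR-1228* and miR-183, and above both subclones for miR-652, miR-23a, miR-27a, miR-210 and miR-1237.

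Other miRNAs named by the fixed rule were apart from both parental arrays in both subclones without passing the threshold. On the rising side were miR-625 (log2 fold change 1.46 ± 0.176 SE, adjusted p = 0.0673 by limma), miR-7 (1.25 ± 0.148, adjusted p = 0.0673), miR-101 (1.24 ± 0.306, adjusted p = 0.204), miR-7-1* (1.15 ± 0.375, adjusted p = 0.244), miR-181a (0.86 ± 0.171, adjusted p = 0.162), miR-574-5p (0.78 ± 0.192, adjusted p = 0.204), miR-181d (0.68 ± 0.0916, adjusted p = 0.0767) and miR-374a (0.66 ± 0.0893, adjusted p = 0.0767). On the falling side were miR-766 (-1.11 ± 0.136, adjusted p = 0.0673), miR-223, a miRNA of myeloid cells (-1.31 ± 0.334, adjusted p = 0.213), and miR-1225-3p (-0.99 ± 0.154, adjusted p = 0.0945). Of these, miR-625, miR-7, miR-181d, miR-374a and miR-766 passed at the common limit (adjusted p = 0.0378 each). miR-338-5p, miR-33b* and miR-149 also met the rule on the falling side, with resistant values under the common limit on at least 1 array and adjusted p of 0.235, 0.235 and 0.273. miR-150, a miRNA of mature lymphocytes, was measured on the parental arrays alone, at -0.84 and 2.63, and has no fold because its parental mean lies under the common limit (adjusted p = 0.256).

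By camera at the preset correlation, the miR-181 family was the 1 list of the 16 tested that passed (adjusted p = 0.036), while fry passed 3. With an estimated correlation it did not pass (p = 0.087, adjusted p = 0.943), with 1 probe per precursor its adjusted p was 0.0506, and no list passed by camera without parental replicate 1, parental replicate 2 or the 100 nM array (1, 2 and 5 at an unadjusted p under 0.05). All 5 tested members were higher on the fitted scale, with a median log2 fold change of 0.73, and miR-181c passed on its own, with 3 passing when adjusted over the list alone. Cross-hybridization among family members was not examined, so the members are not shown to be independent signals. In the 200 nM subclone miR-181a stood at 10.09 and miR-181a* at 7.37, against 9.41 and 6.28 on both parental arrays, and in the 100 nM subclone at 10.44 and 6.66. miR-181b, at 8.35 and 8.21 in the parental arrays, read 9.03 in the 100 nM and 8.35 in the 200 nM subclone (log2 fold change 0.41 ± 0.308 SE). For each subclone alone, the family's median of 0.75 and 0.68 lay at percentiles 99.4 and 99.6 of random lists matched on level.

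The miR-23/27/24 clusters held 5 measured members that went apart. miR-23a and miR-27a fell, over all miRNAs and adjusted over the list alone, while miR-24 (-0.42 ± 0.104 SE), miR-23b (0.43 ± 0.190) and miR-27b (0.07 ± 0.184) did not pass. camera gave this list an adjusted p of 0.362, while fry, which tests whether the members move on balance 1 way, gave 0.0066. fry gave the same adjusted p to the miR-181 family and to the oncogenic miR-17~92 cluster, whose 9 members had a median of 0.15 (camera adjusted p = 0.293). None of the 9 passed, with miR-20a* at 0.60 ± 0.136, miR-17* at 0.55 ± 0.0900, and miR-19a at 9.79 on all 4 arrays.

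In the other tested lists, camera adjusted p ran from 0.75 up and fry adjusted p from 0.293 up. Medians of the log2 fold change were -0.26 for the 3 members of the miR-106a cluster, 0.07 for the 5 of the miR-106b cluster, 0.16 for the 10 of the let-7 family, -0.15 for the 4 of the miR-29 family, 0.027 for the 10 of the miR-15/16 family and -0.015 for the 7 of the miR-30 family. They were 0.20 for the 6 NF-kB responsive miRNAs, 0.055 for the 7 T-ALL oncogenic miRNAs, 0.35 for the 11 lymphoid miRNAs, 0.24 for the 11 tied to bortezomib response in myeloma, -0.17 for 3 of the chromosome 14q32 cluster, -0.60 for 3 of the X-linked miR-513 genes and 0.16 for 3 neuronal miRNAs. At the common limit the medians became -0.12 for the miR-106b cluster, 0.098 for let-7, 0.097 for the NF-kB list, 0.17 for the lymphoid list and 0.037 for the myeloma list. The mean and the median differed in sign for let-7 (mean -0.12), the T-ALL list (-0.41), the chromosome 14q32 list (0.051) and the X-linked list (0.000403). Both tests of the miR-106b cluster, and fry for the myeloma list, pointed down against a median above 0. No member of these passed over all miRNAs or adjusted over the list alone, except miR-27a, which is in the myeloma list. miR-21, at 6.88 and 6.80 on the parental arrays, differed by 0.24 ± 0.0902 (adjusted p = 0.265), and miR-155, at 7.37 and 7.40, by -0.002 ± 0.121 (adjusted p = 1.0).

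Lists with fewer than 3 tested members were not tested as groups. In the hypoxia and stress list miR-210 was the 1 tested member and fell. miR-26b passed when adjusted over its list of 2 alone (log2 fold change -0.63 ± 0.0895), and miR-26a did not (0.19 ± 0.255). miR-221 stood at 0.53 ± 0.291, while miR-222 was under the common limit on both parental arrays and read 3.44 in the 100 nM and 2.80 in the 200 nM subclone (adjusted p = 0.268). Of markers of other cell types, no member of the epithelial, liver, muscle, erythroid and platelet lists was measured on any array, nor was any of the miR-34 and miR-449 family. No fibroblast and smooth muscle marker was measured on a resistant array, and 1 was on a parental array. miR-223 of the myeloid list, miR-126 of the endothelial list, miR-371-5p of the pluripotent list (0.65 ± 0.302) and miR-512-3p of the chromosome 19 cluster did not pass (adjusted p = 0.213, 0.348, 0.326 and 0.595).

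In the 100 nM subclone against the parental line, the rule for size led with miR-181c, miR-595, miR-625, miR-630 and miR-7 on the rising side. miR-630 read 9.35 against 8.21 and 8.03, but did not pass (adjusted p = 0.112). On the falling side the rule took miR-933, miR-33b*, miR-338-5p, miR-129* and miR-129-3p, all with a value under the common limit in this subclone and none past the threshold (adjusted p from 0.103 to 0.204). Of 188 miRNAs, 37 passed in the 3-group limma fit, 20 higher and 17 lower, and 13 of these had a fitted difference of at least 2-fold. For miR-1228*, miR-183 and miR-1237 that difference rests on floor values and is under 2-fold from the common limit. The 37 include 10 of the 12 above, and among the others miR-181a (10.44 against 9.41 on both parental arrays, adjusted p = 0.0349), miR-15b (8.21 against 9.35 on both, adjusted p = 0.0349) and miR-363 (6.21 against 7.44 and 7.49, adjusted p = 0.039) were at least 2-fold apart. Of the 37, 26 had equal values on the 2 parental arrays (70.3%, against 21.8% of all tested miRNAs), and without such miRNAs none passed in the limma fit (25 at an unadjusted p under 0.05). With the spread of the fit of 2 arrays against 2, 10 passed.

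In the 200 nM subclone against the parental line, miR-181c, miR-595, miR-625, miR-7-1* and miR-7 led on the rising side. miR-7-1* read 5.03 against 3.77 and 3.30 (adjusted p = 0.194). On the falling side were miR-125a-3p, miR-223, miR-126, miR-210 and miR-27a. miR-223 fell from 10.55 on both parental arrays to 8.87 (3.21-fold, adjusted p = 0.0229), and miR-126, an abundant miRNA of endothelial cells, from 5.73 on both to 4.07 (3.14-fold, adjusted p = 0.0229). miR-125a-3p read 0.70, under the common limit, against 4.26 and 4.14 (adjusted p = 0.0259). Of 188 miRNAs, 43 passed, 27 higher and 16 lower, and 15 had a fitted difference of at least 2-fold, which adds miR-181a* (7.37 against 6.28) and miR-513b (2.74 against 3.94) to those named. For miR-182, miR-1228*, miR-183 and miR-1237 that difference rests on floor values and is under 2-fold from the common limit. Of the 43, 31 had equal parental values (72.1%), none passed without such miRNAs in the limma fit (22 at an unadjusted p under 0.05), and 10 passed with the spread of the fit of 2 arrays against 2.

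The 200 nM and 100 nM subclones were also set against each other, 1 array against 1, with the spread of the parental pair. miR-126 was lower in the 200 nM subclone (log2 difference -1.20, adjusted p = 0.0355 by limma), as were miR-223 (-0.76, adjusted p = 0.0355) and miR-125a-3p (-3.33, adjusted p = 0.045), the last with a value under the common limit. miR-363 was higher in the 200 nM subclone by 1.19 (adjusted p = 0.0469). Of the let-7 family, let-7a, let-7f and let-7g were higher by 0.85, 0.36 and 0.60, and of the miR-29 family miR-29a and miR-29b were lower, with differences of -0.72 and -0.95 (adjusted p = 0.0355, except let-7f at 0.0404). The members of the miR-15/16 family miR-15a and miR-15b were higher by 0.48 and 0.75 (adjusted p = 0.036 and 0.0355). Two-sided limma tests called 30 of 188, 18 higher and 12 lower, 3 of them at least 2-fold apart. Each subclone has 1 array, 27 of the 30 had equal parental values (90.0%), and none passed without these (10 at an unadjusted p under 0.05). With the spread of the fit of 2 arrays against 2 none passed either (0 at an unadjusted p under 0.05). That spread contains the difference between the subclones itself, so this outcome was fixed in advance and says nothing about the difference.

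The other differences between the subclones named by the rule did not pass. miR-630 read 9.35 in the 100 nM and 7.28 in the 200 nM subclone (adjusted p = 0.0929) and miR-188-5p 6.04 and 4.80 (adjusted p = 0.126). let-7c, miR-15b*, miR-933, miR-760 and miR-155* on the higher side, and let-7f-1* and miR-423-3p on the lower side, each had a value under the common limit in 1 subclone (adjusted p from 0.169 to 0.825).

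The changes of the subclones were positively correlated. Over the 145 miRNAs measured on all 4 arrays, the log2 fold changes of the subclones had a Pearson correlation of 0.550 and a Spearman correlation of 0.554 across miRNAs, which are not independent replicates, and 100 (69.0%) had the same sign. Simulated unchanged subclones sharing a simulated parental pair gave a Pearson correlation of 0.313 and 60.6% of the same sign. The 41 miRNAs with equal parental values got no noise in these simulations. How that shifts the simulated correlation and covariance was not tested. The simulated share of the same sign leaves out miRNAs with equal parental values, while the observed 69.0% includes them. The covariance was 0.370, ± 0.0775 (bootstrap SD over miRNAs), against 0.066 in these simulations. The simulated covariances spread widely, and the upper limit of their range, leaving out the most extreme simulations, was 0.262. The bootstrap SD does not include that spread. With a different parental array for each subclone, the correlation was 0.554 or 0.287 and the covariance 0.372 or 0.233, by the pairing. Of the calls of the subclones, 15 were higher in both and 10 lower in both, and 5 went opposite ways. Independent lists drawn from all 188 would share 2.87 and 1.45. Simulations with no effect shared 0, because few unchanged miRNAs are called there at all. Neither value allows for equal parental values, which 26 of the 37 calls and 31 of the 43 had. Part of the excess may come from the shared parental arrays, and the overlap alone cannot show agreement beyond them.

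Both subclones were at least 2-fold from both parental arrays, in the same direction, for 25 miRNAs, 14 higher and 11 lower. The other 2 ways of pairing the arrays gave 15 and 4. At the common limit the count was 11, 6 higher (miR-96, miR-22, miR-181c, miR-595, miR-625 and miR-7) and 5 lower, against 0 and 1 for the other pairings. Of the 25, 17 had a value under the common limit.

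**Figure D2:**
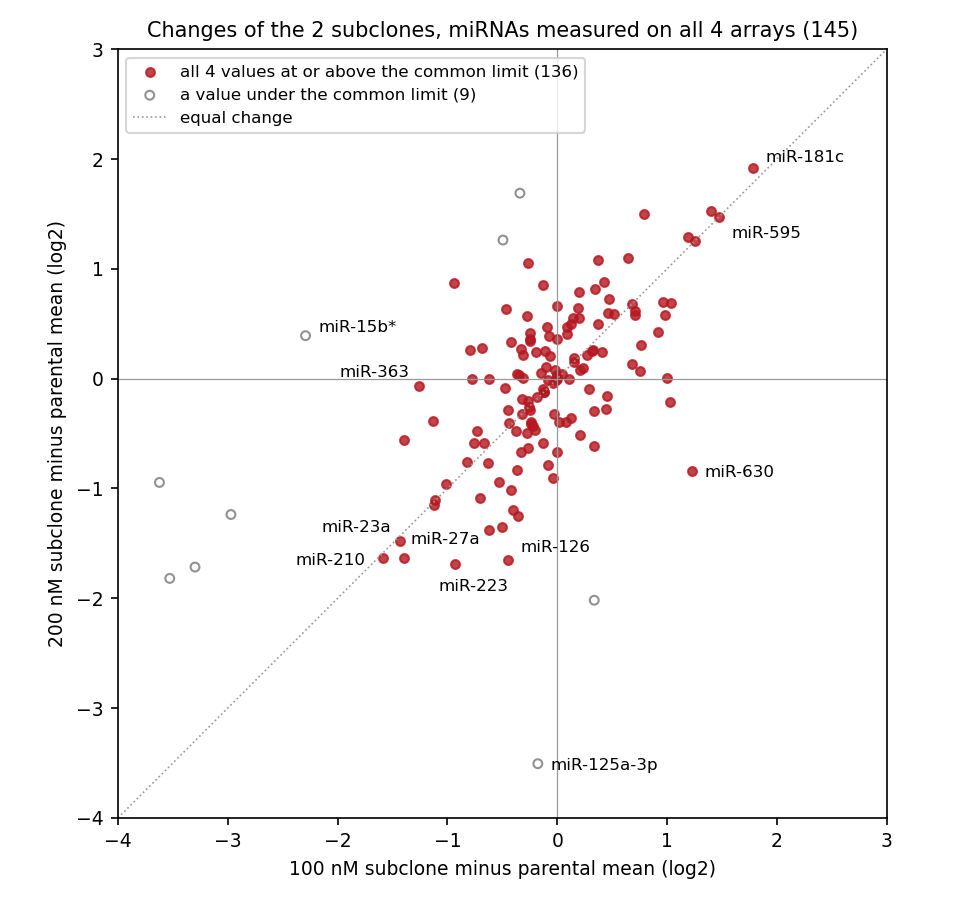
Log2 change from the parental mean in the 100 nM subclone (horizontal axis) and in the 200 nM subclone (vertical axis) for the 145 miRNAs measured on all 4 arrays, 1 point per miRNA; filled points have all 4 values at or above the common limit (136), open points have a value below it (9), and the dotted line marks equal change. miR-181c and miR-595 lie at the upper right, miR-210, miR-23a and miR-27a at the lower left, and miR-630 is higher in the 100 nM and lower in the 200 nM subclone.

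The authors' deposited table lists 47 miRNAs with a change of at least 2-fold, 28 for the 100 nM subclone (18 higher, 10 lower) and 33 for the 200 nM subclone (6 higher, 27 lower). In the authors' deposited table, 14 appear for both subclones, 6 higher in both (miR-7-1*, miR-19b-1*, miR-101, miR-181c, miR-595 and miR-625), 7 lower in both and miR-630 with opposite signs. For miR-181c the authors' deposited table gives log2 ratios of 1.96 and 1.66 at 100 nM and 200 nM, and for miR-23a -1.11 and -1.63. Of the 61 entries of the authors' deposited table, 56 had the same sign as the log2 fold change computed here and 5 the opposite sign, all 5 among the 19 entries with a value under the common limit. The median gap in size was 0.19 over the 42 entries whose miRNA had no value under the common limit and 2.11 over these 19. Of the 12 miRNAs past the threshold here, 6 are in the authors' deposited table. miR-96, miR-22, miR-182, miR-183, miR-1228* and miR-1237, each at the floor on the arrays of 1 kind, are not. In the authors' deposited table miR-21* carries the same ratios as miR-210, -1.41 and -2.11, although miR-21* was at the floor on all 4 arrays.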

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

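The test of equal parental values in this part was chosen only after the result was seen. The limma test of the difference between the subclones, 1 array against 1 with the spread of the parental pair, passed for miR-126 (200 nM minus 100 nM, log2 -1.20), miR-223 (-0.76), miR-181a (-0.35) and miR-125a-3p (-3.33), with adjusted p of 0.0355, 0.0355, 0.0404 and 0.045. For the first 3 the parental values are equal, so that spread is 0 before moderation. With the spread of 2 arrays against 2 no miRNA passed in limma (0 unadjusted), which was fixed in advance, because that spread contains the difference tested. Of these, miR-126, miR-223 and miR-125a-3p (under the common limit in the 200 nM subclone, so -3.33 is not a size) were lower than both parental arrays in both subclones, with the 200 nM subclone farther away, and miR-181a was higher in both, with the 100 nM subclone farther away. The subclones lay on opposite sides of the parental arrays for 5 miRNAs called in each subclone and in their difference (adjusted p = 0.0355 each), all with equal parental values. let-7a (0.85), let-7g (0.60) and miR-801 (0.61) were higher in the 200 nM and lower in the 100 nM subclone, while miR-29a (-0.72) and miR-29b (-0.95) went the other way.

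miR-630 lay above both parental arrays by at least 1.14 in the 100 nM and below them by at least 0.75 on the log2 scale in the 200 nM subclone (differences -0.75 and -0.84 to the nearer array and to the mean). Its difference of -2.07 did not pass (adjusted p = 0.0929). miR-15b* (2.68, with a value under the common limit and so not a size, adjusted p = 0.169) and miR-188-5p (-1.24, adjusted p = 0.126) also lay on opposite sides of the parental arrays, and their differences did not pass.

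The single-subclone calls may rest in part on equal values of the parental arrays. Of the calls of the 100 nM subclone, 70.3% had equal parental values, against 21.8% of all tested miRNAs, and of those of the 200 nM subclone 72.1%. Quantile normalization gives the same value to equal ranks, so 2 arrays with similar ranks share values exactly and show no spread. Without these miRNAs 0 calls remained in each of the 3 comparisons, in a fit whose variances were moderated anew. The fold changes of the other called miRNAs, such as miR-96 and miR-22, were the same there. Their lost calls therefore do not show that they rested on equal parental values. Whether let-7, miR-29 and miR-126 differ between the subclones beyond array noise stays open, since each subclone has 1 array, and a difference between the subclones or their drug levels was not tested apart from it.

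Of the viral probes, which entered no comparison, 3 gave signals in the 100 nM subclone above the parental level, and kshv-miR-K12-10b was measured on parental replicate 1 alone (-2.27, under the common limit). A probe for kshv-miR-K12-3 read 5.42, against 5.18 and 5.23 in the parental arrays and 4.57 in the 200 nM subclone. A probe for hsv1-miR-LAT read 4.48, against 3.38 and 2.36, and lay at the floor in the 200 nM subclone. A probe for hsv1-miR-H1 read -0.89, under the common limit, and lay at the floor on the other 3 arrays.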

How the results depend on the processing

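Of these settings, the common limit and the leaving out of equal parental values were chosen after seeing the data. Over the named miRNAs, 637 log2 fold changes under alternatives kept their direction and, where a p existed, their side of the threshold, 42 no longer passed, 23 newly passed and none changed sign. The 637 include single-subclone changes with a parental array left out, which have no p. Their direction was fixed in advance, because the rule names miRNAs that lie on the same side of both parental arrays. The same holds for the named changes of resistant against parental with any array left out. An intensity trend or robust moderation leaves every log2 fold change as it was, so direction could not change there either. Quantile normalization of the 4 arrays gave 39 and 44 for the 100 nM and 200 nM subclones, 34 for their difference and 28 miRNAs at least 2-fold apart, and median scaling gave 10 for resistant against parental (without miR-27a and miR-652), 45 for the 200 nM subclone and 27 for the difference. For resistant against parental (12), the count was 19 with an intensity trend, 20 at an adjusted p of 0.1, 48 with the spread of the parental pair alone and 0 to 43 with an array left out (0 without parental replicate 2, 23 unadjusted by limma, and 7 without replicate 1). At the common limit it was 18, of which 11 were among the 12, with the filter on the mean level 10 (without miR-27a and miR-652) and with robust moderation 11 (without miR-652). For the 100 nM subclone (37), the 200 nM subclone (43) and their difference (30), no filter left 0, 0 and 0 (62, 77 and 54 at an unadjusted p under 0.05, limma), and leaving out equal parental values 0, 0 and 0 (25, 22 and 10 unadjusted). A fitted fold of at least 2 left 13, 15 and 3, some of the 13 and 15 only through floor values. The spread of 2 against 2 left 10, 10 and 0 (0 unadjusted for the difference). The last 0 was fixed in advance, because that spread contains the difference between the subclones. The filter on the mean level gave 16 for the 100 nM subclone and 0 for the difference (68 unadjusted). An adjusted p of 0.1 gave 68 for the 200 nM subclone, and the common limit 47 for the difference. Without a parental array these 3 fits have no residual degrees of freedom, so no count exists. The 25 miRNAs at least 2-fold apart became 10 when measured on all 4 arrays, 11 at the common limit, 11 at 4-fold and 30 to 44 with 1 parental array. The covariance (2.66 over all 188) was 0.833 with no filter, 0.370 for miRNAs measured on all 4 arrays, 0.943 with 1 added to linear values, 0.434 at the common limit and 2.22 to 4.77 with 1 parental array, so its size rests on dim miRNAs. Lists past the threshold (1) became 3 with no filter, 0 with an estimated correlation (0 unadjusted), 3 with fry, 0 with 1 probe per precursor (1 unadjusted) and 0 to 2 with an array left out. Fewer arrays or miRNAs enter the fits with an array left out or a stricter filter, and for the rest the cause was not tested. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers. Signals under the common limit carry no size, which limits all folds of dim miRNAs.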

Other observations

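The tests on miR-96 with its companions and on dim miRNAs were chosen only after the results were seen; the test on neighbouring genes was not. The lymphoid list stood high in the 200 nM subclone, where its median log2 change of 0.66 lay at percentile 99.7 of random lists matched on level, against percentile 86.7 in the 100 nM subclone. That median is the change of miR-142-3p, from 11.32 on the other 3 arrays to 11.98, where it exchanged values with another miRNA, so quantile ranks fix its size. miR-142-5p read 8.27 against 7.40 and 7.37 in the parental arrays (adjusted p = 0.0281). The miR-15/16 and let-7 families lay at percentiles 94.7 and 91.9 in the 200 nM subclone and 22.9 and 33.1 in the 100 nM subclone, and the miR-29 family at 5.98 and 65.3. The X-linked miR-513a-5p read 4.72 on both parental arrays, 4.36 in the 100 nM and 3.89 in the 200 nM subclone, and miR-513b 3.94, 3.54 and 2.74 (adjusted p of the difference between subclones 0.036 and 0.0355). Each subclone has 1 array, so the percentiles describe these arrays.

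miR-96, miR-22, miR-182, miR-183 and miR-1228* were measured in both subclones and on neither parental array. Of 29 other miRNAs in the range of brightness of miR-96 and miR-22 that parental replicate 2 measured, replicate 1 missed 0 (upper 95% limit 9.81%). This bounds misses of replicate 1 alone, among miRNAs that both subclones measured in that range. Replicate 2 missed miR-32*, which read 3.44 on replicate 1, 4.58 in the 100 nM and 4.36 in the 200 nM subclone. Replicate 1 missed a miRNA that read 4.17 on replicate 2 and was measured on no other array. A miRNA missed on both parental arrays could not enter the 29, so lower sensitivity shared by the parental arrays stays open. For miR-96 a floor effect is argued against, since its smallest difference at the common limit was 3.11. Between parental replicates, over 148 probes measured on both, the 95th percentile was 0.879 and the largest value 1.48. These 148 leave out probes at the floor on 1 parental array. For miR-22, at 2.13, a floor effect stays open. The miRNA at 4.17 on replicate 2 alone was brighter than miR-22 in the 200 nM subclone (4.12). miR-96 was brighter than that miRNA in both subclones (5.10 and 5.52). For miR-182 (0.95), miR-1228* (0.91) and miR-183 (0.59) neither lower sensitivity nor a floor effect can be told apart from a gain. Over the 18 parental probes as dim as these the 95th percentile was 1.15, and only 2 other miRNAs in their range could show a miss on replicate 1 (upper 95% limit 77.6%). RNA of epithelial cells, which also make the miR-96 cluster, is argued against, since 0 of 11 epithelial list members were measured in either subclone. A gain of miR-96 and miR-22 tied to the resistant subclones stays open as a hypothesis, found and tested on the same arrays.

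Changes of dim miRNAs computed here differed from the authors' deposited ratios. Of the 25 miRNAs at least 2-fold apart in all 4 differences, 68.0% had a value under the common limit. Over the 19 entries of the authors' deposited table with such a value, raising it to the limit cut the median gap to their ratio from 2.11 to 0.62. A candidate explanation is averaging with the floor during quantile normalization, because the arrays differ in how many probes lie at the floor. A true loss of miR-33b*, miR-338-5p, miR-129* or miR-129-3p in the subclones was not tested apart from it.

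Neighbouring miRNA genes may change together. Over 55 pairs of tested miRNAs whose genes lie within 10000 bases of each other, the mean absolute difference of their log2 fold changes was 0.894, against 1.78 for random pairings (permutation p = 0.0106). At the common limit the difference was 0.348 against 0.737 (permutation p = 8e-04), and 0.353 against 0.812 over miRNAs measured on all 4 arrays (permutation p = 0.001). Shuffling genes within bins of level gave a permutation p of 0.0067, 0.0016 and 0.0107 in the same order. Of the pairs, miR-23a and miR-27a stood close (-1.45 and -1.51), while miR-181c and miR-181d (1.85 and 0.68) were farther apart.

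The authors' deposited ratios sit at a shifted level against the deposited signals. Over entries with no value under the common limit, the authors' deposited ratio was above the log2 fold change computed here in 17 of 18 for the 100 nM subclone (median gap 0.32) and below it in 23 of 24 for the 200 nM subclone (-0.18). The shift held for entries of both directions, with 3 of 4 falling entries above at 100 nM and 6 of 6 rising entries below at 200 nM. In the deposited signals, of 136 miRNAs with no value under the limit, 9 were at least 2-fold higher and 9 lower in the 100 nM subclone, and 9 higher and 13 lower in the 200 nM subclone. Of the entries of the authors' deposited table with no value under the limit, 14 were higher and 4 lower at 100 nM, and 6 higher and 18 lower at 200 nM.

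Few miRNAs were measured on a single array, 10 and 6 in the parental replicates, 7 in the 100 nM and 4 in the 200 nM subclone. The highest of these read 3.02 and 4.17 in parental replicates 1 and 2, 2.33 in the 100 nM and 3.98 in the 200 nM subclone. A signal on 1 array alone thus reached the level of miR-22 in the 200 nM subclone (4.12).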
